A study of Mus musculus with 6 samples.

How the data were processed

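Samples labelled as 3 wild type and 3 Hoxc6 knockout mouse prostates, all collected at 32 weeks of age, were profiled. They were run on 1-colour Illumina mouse bead arrays, 1 array per labelled sample. The labels name no animals, so it is not shown that each array holds a separate animal. Per the labels' protocols, the tissue was flash frozen, total RNA was isolated with an RNeasy kit and 50 ng of it was labelled with biotin by the TotalPrep method. The deposited values are intensities on a linear scale, 1 per probe and array, made with BeadStudio per the submitters' processing notes; the version is not given in the sources used here. Values below 0 were present on every array, as background subtraction leaves them, and no detection p-values were used here. Whether the authors scaled the arrays to each other is not given in the sources used here: the 75th percentiles lay between 66.0 and 69.6 on the 6 arrays, whereas the medians lay between 7.1 and 11.7 and the brightest 1% of probes began between 3404 and 5185. How the background was subtracted also stays unknown.

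The table held 46628 probes, named by array identifiers alone. A probe was given a gene only where its identifier carried a 5- or 6-digit number after 1 or 2 leading zeros that is a gene number in the NCBI RefSeq annotation of the mouse assembly GRCm38.p6, a RefSeq accession in that annotation, or the name of a mitochondrial gene. That reading of the number is an inference from the form of the identifier and was checked against the values. Of 438 probes read as olfactory or vomeronasal receptors, 4 had a mean intensity over 32, against 71 of 79 read as cytosolic ribosomal proteins. The same reading of identifiers without leading zeros matched 11.3% of 16482 numbers, and 13 of 29 such olfactory probes were over 32, so those identifiers were left unnamed. In all, 9815 probes named 1 gene, none named several and 36813 were left without a gene; 8109 genes were named, 1501 of them by more than 1 probe. Of the 11857 identifiers with leading zeros 9796, or 82.6%, matched. RIKEN clone, GI and transcript cluster identifiers were not named. Probes whose identifier spells out an antigen receptor gene segment or a ribosomal RNA were described as classes, which was decided after the values were seen. The annotation served for names and for which genes neighbour each other, and no coordinates are given.

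The 6 arrays were quantile normalised to each other, values under 32 were set to 32 and log2 was taken (log2 of the floor is 5). A detection limit was set per array at 1.645 times the root mean square of its negative values, which gave limits between 2.5 and 10.1 intensity units. A probe was tested if it was above the limit on at least 3 of the 6 arrays, which 32838 probes were. Of these, 15223 sat at the floor on all 6 arrays, carried no test and were left out, which left 17615 tested probes, 4764 of them naming 4255 genes. Knockout was compared with wild type by lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05 on the adjusted p. The replicate numbers were not used as a block. Where a group lay at the floor on all its arrays, the fold is a bound and is given as at least that large. With only some arrays of the lower group at the floor, and none of the other, the printed change is also a bound. Levels are normalised log2 intensities, given as mean ± SD over 3 arrays.

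Gene lists were written before the data were examined, as were the tests, the rule for named genes and all alternatives except those said to be added. There were 30 lists: reported HOXC6 targets; Hox genes; the Notch, Wnt, BMP and TGF-beta, and FGF, IGF and PDGF pathways; androgen response; prostate secretory products; markers of seminal vesicle, luminal and basal epithelium, urothelium, smooth and skeletal muscle, adipocyte, fibroblast and matrix, endothelium, nerve and Schwann cell, neuroendocrine cell, T cell, B and plasma cell, macrophage and MHC class II, and red blood cell; and interferon response, proliferation, apoptosis, immediate early and stress, endoplasmic reticulum stress, cholesterol and fatty acid synthesis, and oxidative phosphorylation. Each list with at least 4 tested genes was tested with camera of limma, preset correlation 0.01, on the brightest tested probe of each gene, two-sided, with Benjamini-Hochberg adjustment over the 18 lists that qualified. The named genes were Hoxc6; the 12 largest changes in each direction among probes past the threshold that name 1 gene and keep all 3 knockout arrays on one side of all 3 wild type arrays, passing over RIKEN and predicted names (1 in each direction); up to 4 genes with the smallest p from each list past the list test; all reported targets; and up to 2 genes with the smallest p from the Hox, Notch, Wnt, BMP, FGF, androgen, apoptosis and cell type lists. No probe was named Hoxc6, so its level is not analysed here.

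Alternatives were no normalisation, scaling to the 75th percentile, floors of 16 and 64, no floor (the value minus the lowest of the table plus 50), no filter, a filter asking for all 6 arrays, an intensity trend with a robust prior, array weights, the replicate number as a block, and leaving out each array in turn; for lists also the mean of all probes of a gene, an estimated correlation and fry. Averaging knockout replicates 1 and 3, averaging all 3 knockout arrays, and leaving out RIKEN clone probes were added after seeing the data. The steps were tested on simulated data for this comparison over 17328 tested probes: of 100 probes changed by 2 on the log2 scale 93 were called, of 100 changed by 1 on that scale 43 were called, and 6 of 142 calls were false. The simulated noise was independent between arrays and probes and had the same SD in both groups, and only brighter probes were changed. In the real data the knockout arrays were closer to each other than the wild type arrays. Of the real calls, 120 lay at the floor on all wild type arrays and 33 on all knockout arrays. The simulated rates may therefore not hold for the real calls. Arrays give no read depth, and the number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.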

Results

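Gene expression was measured in samples labelled as 3 Hoxc6 knockout and 3 wild type mouse prostates, collected at 32 weeks of age. Each labelled sample had 1 bead array of 46628 probes, and the labels name no animals. Hoxc6 encodes a homeobox transcription factor, and the comparison asks which transcripts differ in the prostate when it is lost. Summed intensity ranged from 9123021 to 12621353 per array. The median intensities were 7.1, 11.7 and 9.1 on wild type arrays 1 to 3 and 10.2, 9.4 and 11.7 on knockout arrays 1 to 3. After normalisation 32.8% of the probes lay above the floor on each array. No probe was named Hoxc6, so the genotype in the labels was not checked against its own transcript.

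Knockout prostates had higher transcripts of Mt3, Aqp9 and Ighm and lower transcripts of Tcaf3 and Mia than wild type prostates. Mt3, which encodes a metallothionein, rose 20.3-fold, from 7.33 ± 0.57 in wild type to 11.68 ± 0.85 in knockout prostates (log2 intensity, SD, n = 3 each; limma adjusted p = 0.0129). Aqp9, a water and glycerol channel, lay at the floor on all 3 wild type arrays and at 8.54 ± 0.19 in the knockout, at least 11.7-fold higher (limma adjusted p = 0.000395); this bound, a change of 3.54 on the log2 scale, was 2.54 with a floor of 64. Mia, a small secreted protein, fell by 2.87 on the log2 scale, from 11.12 ± 0.36 to 8.26 ± 0.18 (limma adjusted p = 0.00481). Tcaf3, a TRP channel-associated factor, fell by 3.21 on the log2 scale, from 10.84 ± 0.72 to 7.63 ± 0.13 (limma adjusted p = 0.0123). Aqp9, Ighm and Mia passed in each of the 6 fits without 1 array, whereas the calls of Mt3 and Tcaf3 ended without knockout replicate 1 (changes 4.07 and -3.30, limma adjusted p = 0.0784 and 0.0786) and without knockout replicate 3 (changes 4.19 and -3.17, 0.0815 for both), with changes about as large as over all arrays. Of all 38 named genes past the threshold, 33 lost it in each of these 2 fits. All 6 fits still counted the knockout arrays as separate samples, so passing them does not show that the samples are independent. With the replicate number as a block the call of Ighm ended (limma adjusted p = 0.0526), while those of Aqp9 and Mia held. In all, 1202 of 17615 tested probes passed the threshold, 803 higher and 399 lower in the knockout. Among the 4255 tested genes with a name, 85 were higher and 118 lower. All 3 knockout arrays lay on one side of all 3 wild type arrays in 27.5% of the tested probes. For 6 independent samples chance gives 10% as the expectation for a probe without ties. Probes vary together, so the observed share can lie far from 10% by chance. The labels also do not show that these samples are independent.

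The other large rises among named genes covered several functions. Crygc, a lens crystallin, was at least 7.97-fold higher and Myh7, the slow myosin heavy chain, at least 4.24-fold higher, both at the floor on all wild type arrays. Ces5a, a carboxylesterase, rose 8.5-fold and was at the floor on 2 of the 3 wild type arrays. Upk3b, a uroplakin, rose 5.23-fold, also with 2 wild type arrays at the floor. Cux2, a homeobox factor, rose 5.35-fold with 1 wild type array at the floor. Trf, the iron carrier transferrin, rose 4.81-fold, Srpx 4.4-fold and Acer2, a ceramidase, 3.81-fold. Ighm, the immunoglobulin mu heavy chain, rose 4.22-fold, from 10.58 ± 0.19 to 12.66 ± 0.05 (SD, n = 3 each), and the light chain gene Iglv1 rose 3.64-fold. The limma adjusted p of these 10 genes ranged from 0.000299 for Crygc to 0.0313 for Cux2. For genes at the floor the size moved with it. The changes on the log2 scale are bounds where wild type arrays lay at the floor, whether all or only some of them. With floors of 16 and 64 they were 3.75 and 2.21 for Ces5a in place of 3.09, and 4 and 2 for Crygc in place of 3. They were 3 and 1.08 for Myh7 in place of 2.08, and 2.90 and 1.72 for Upk3b in place of 2.39. The call of Myh7 ended with a floor of 64 (limma adjusted p = 0.0591) and that of Upk3b with a floor of 16 (0.0559). That of Iglv1 ended without normalisation (change 1.59 in place of 1.86, 0.0575) and with 75th percentile scaling (1.59, 0.0641), and Cux2 had a change of 1.57 in place of 2.42 with no floor.

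Among the other large falls, Chd4, a chromatin remodeller, fell by 1.66 and Rbbp4, a histone-binding protein, fell by 1.49 on the log2 scale. A second, brighter probe of Chd4 had a change of 0.42 (limma adjusted p = 0.25), so the probes of this gene differed. On the log2 scale, Nlrp10 fell by 2.20, Asph fell by 1.98, Cadps, which acts in vesicle release, fell by 1.94, Shisa4 fell by 1.82 and Neurl1a, a ubiquitin ligase, fell by 1.73. A second probe of Asph had a change of -0.43 (limma adjusted p = 0.3). Fam131a fell by 1.53, the fibrillar collagen gene Col3a1 fell by 1.61 and the basal keratin gene Krt17 fell by 1.5. The limma adjusted p of these 10 genes ranged from 0.00848 for Rbbp4 to 0.0487 for Neurl1a. Nlrp10 and Cadps lay at the floor on 2 of the 3 knockout arrays and Chd4 and Fam131a on 1. With a floor of 64 the calls of Nlrp10 (change -1.28), Cadps (-0.98), Shisa4 (-1.37), Chd4 (-1.01) and Col3a1 (-1.12) ended, with limma adjusted p from 0.0512 for Nlrp10 to 0.191 for Cadps, and Fam131a had a change of -0.91. With no floor those of Cadps (-1.04), Shisa4 (-1.07), Col3a1 (-0.91) and Neurl1a (-1.50) ended, and Asph had a change of -1.31. With a floor of 16 the calls of Neurl1a (-1.73, limma adjusted p = 0.0529) and Col3a1 (-1.61, 0.0526) ended at the changes reported, and that of Col3a1 also without normalisation (-1.63, 0.0517).

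**Figure D1:**
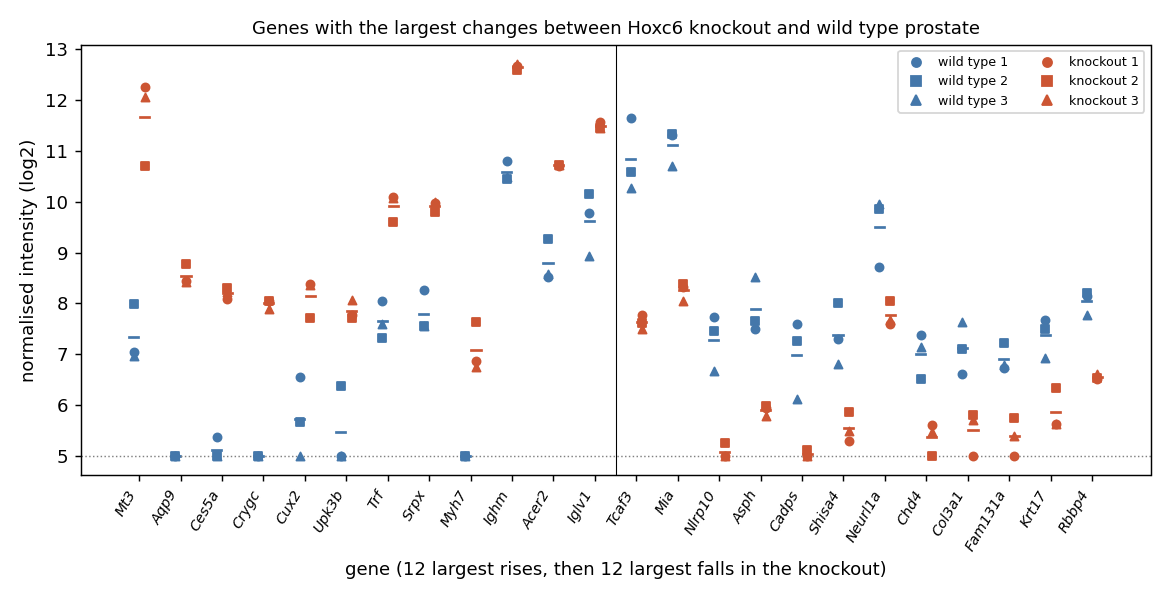
Normalised log2 intensity of the 12 named genes with the largest rises and the 12 with the largest falls in the knockout. Points are single arrays (blue wild type, red knockout, 3 each), short lines are group means and the dotted line is the floor at 5; in each gene all 3 knockout arrays lie on one side of all 3 wild type arrays.

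Of 64 tested probes for variable segments of the immunoglobulin heavy and light chains, 35 rose, none fell and 29 did not pass, with a median change of 1.30 on the log2 scale over all 64, values at the floor taken as 5. The change was below 0 in 10 of those 29. The median over these 64 probes was 5.2, 5 and 5 on the wild type arrays, next to the floor, and 6.64, 6.5 and 6.68 on the knockout arrays. This class was singled out after its values were seen, and no test was run on it as a set. In the fixed list of B and plasma cell markers Ighm was the 1 tested gene of 10, so the list itself was not tested.

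Of 18 gene lists tested, 3 passed the list test. None of these 3 passed with fry, where the adjusted p was 0.089 for fibroblast and matrix and 0.237 for both others. The estimated correlations were 0.455 for fibroblast and matrix, 0.777 for macrophage and MHC class II and 0.416 for cholesterol and fatty acid synthesis genes. The preset was 0.01. The BMP and TGF-beta list had an estimate of -0.049, below the preset, yet its adjusted p with camera also rose, from 0.0526 to 0.747. Correlation among members therefore cannot be the whole reason why no list passed with an estimated correlation. Fibroblast and matrix genes were lower in the knockout (adjusted p = 0.00783 with camera; adjusted p = 0.747 with an estimated correlation). Of its 8 tested genes 2 fell, Col3a1 and Fbln1, a basement membrane fibulin that fell by 0.91 on the log2 scale, and the other 6 did not pass; adjusted over the list alone, 6 of the 8 fell. Col5a1 had a change of -0.88, and Col1a2, at the floor on all knockout arrays, was at least 1.68-fold lower by the means, neither past the threshold over all probes. With a floor of 64 Col1a2 had a change of -0.06 in place of -0.75 (limma adjusted p = 0.721). Macrophage and MHC class II genes were higher (adjusted p = 0.0105 with camera; adjusted p = 0.809 with an estimated correlation). In that list 1 of 7 genes rose, also when adjusted over the list alone: the complement gene C1qa, 1.52-fold. Cd74, the MHC class II invariant chain, had a change of 0.96, H2-Ab1 of 0.54 and C1qb of 0.49, and all 7 were above 0. Cholesterol and fatty acid synthesis genes were higher (adjusted p = 0.0107 with camera; adjusted p = 0.809 with an estimated correlation). Of 15 genes 1 rose, Acly, which makes cytosolic acetyl-CoA, 1.5-fold, and 4 rose when adjusted over the list alone. Without normalisation Acly had a change of 0.32 in place of 0.58 (limma adjusted p = 0.239), and with 75th percentile scaling also 0.32 (0.276); C1qa had a change of 0.51 and an adjusted p of 0.0537 and 0.0517 in these fits. Acaca had a change of 1.17, Lss of 0.66 and Srebf2 of 0.40, whereas 5 members, Insig1 among them, were below 0. Without wild type replicate 3 Col5a1 (change -0.70, limma adjusted p = 0.0397), Col1a2 (0.0351) and Acaca (0.85, 0.0182) passed. Without wild type replicate 1 the adjusted p of the macrophage list was 0.0647, and without wild type replicate 3 that of both other lists was 0.0538.

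**Figure D2:**
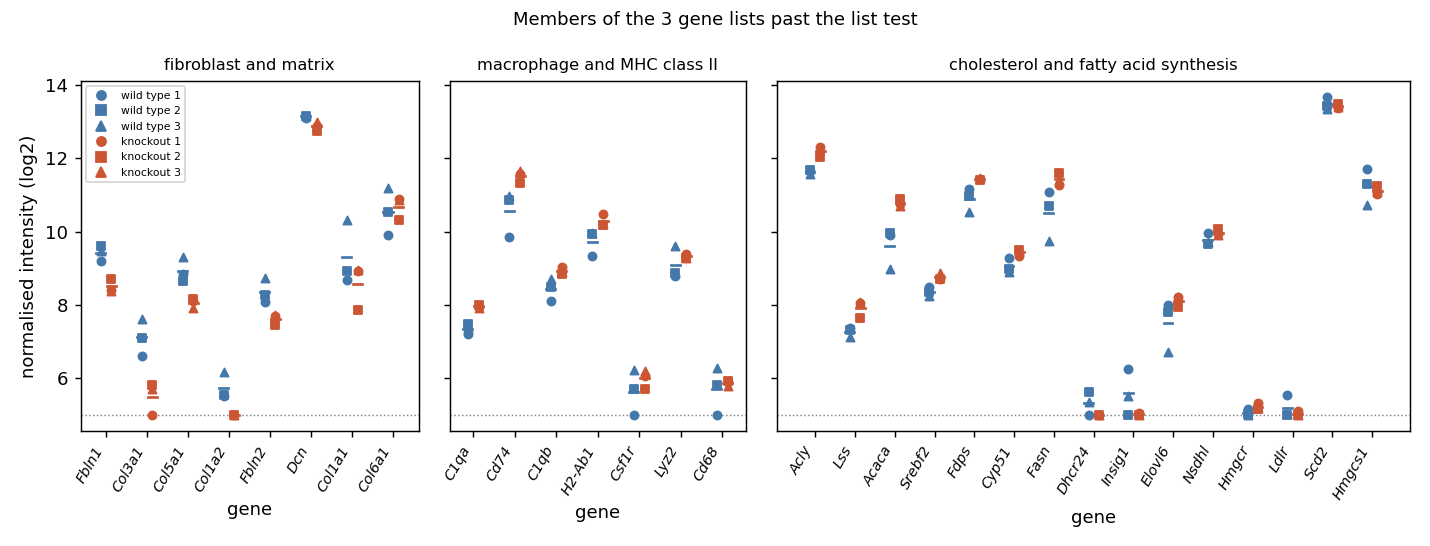
Normalised log2 intensity of each tested member of the 3 lists past the list test, ordered by p within a list. Points are single arrays (blue wild type, red knockout), short lines are group means and the dotted line is the floor at 5; 7 of 8 fibroblast and matrix genes have a lower knockout mean, and 7 of 7 macrophage and 10 of 15 lipid synthesis genes a higher one.

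None of the signalling lists passed the list test with camera. Of the 9 reported HOXC6 targets 2 were tested, and neither passed: Igfbp3 had a change of -0.86 (limma adjusted p = 0.23) and Fgfr2 of -0.52 (limma adjusted p = 0.416). In the BMP and TGF-beta list 2 of 12 genes fell: Ltbp1, which tethers latent TGF-beta to the matrix and fell by 1.37, and Tgfb2, which fell by 1.06 on the log2 scale, and 3 when adjusted over the list alone; the change was below 0 in 10 of the 12. The list had an adjusted p of 0.0526 with camera and 0.011 with fry, and passed in 10 of 21 alternative settings, with adjusted p from 0.011 to 0.747. In the FGF, IGF and PDGF list 2 of 11 genes fell, also when adjusted over the list alone: of the IGF-binding genes, Igfbp5 fell by 1.4 and Igfbp6 fell by 0.83 on the log2 scale (list adjusted p = 0.32 with camera and 0.0332 with fry). A second probe of Igfbp5 had a change of -1.28 (limma adjusted p = 0.0105). In the Wnt list Nkd1, an inhibitor of the pathway, rose 3.21-fold and Sfrp1, a secreted Wnt antagonist, fell by 1.06 on the log2 scale, and 7 of 9 genes did not pass (list adjusted p = 0.866). Of 8 tested Hox genes, none of them from the Hoxc cluster, Hoxd3 rose 2.44-fold and Hoxa7 fell by 1.19 on the log2 scale (list adjusted p = 0.866). Adjusted over the list alone 2 rose and 1 fell. The list result therefore does not cover the Hoxc genes. Sfrp1 lay at the floor on 2 knockout arrays and Hoxd3 on 1 wild type array. With a floor of 64, Hoxd3 had a change of 0.43 in place of 1.29 (limma adjusted p = 0.12) and Sfrp1 of -0.21 (0.338), so both calls ended; that of Hoxd3 also ended with a floor of 16 (1.55, 0.0527). The test of the Hox list pointed up while its median change was -0.02 and its mean -0.024. No gene passed among 8 Notch pathway genes (smallest limma adjusted p 0.0716, Adam17, change -0.55; Maml2 -0.63; list adjusted p = 0.608), 7 androgen response genes (changes of 0.58 for Hpgd and -0.57 for Insig1; list adjusted p = 0.912) or 8 apoptosis genes (changes of -0.62 for Bcl2 and -0.19 for Cdkn1a; list adjusted p = 0.912), although adjusted over the list alone 1 apoptosis gene fell. Without wild type replicate 1 Maml2 (change -0.82, limma adjusted p = 0.0372) and Hpgd (0.68, 0.0389) passed, and without wild type replicate 3 Adam17 (-0.67, 0.0363) and Bcl2 (-0.73, 0.0234).

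Cell type markers gave the following values, in which a number beside a gene name is its change on the log2 scale unless a fold is named. The basal list had 1 of 4 genes past the threshold, Krt17 (list adjusted p = 0.608; Sfn 0.47), and the luminal list none of 8 (0.92; Krt19 -0.67 and Cldn4 0.26, the latter -0.01 without normalisation or with 75th percentile scaling). The endothelial gene Pecam1 fell by 0.82 on the log2 scale, Emcn had a change of 0.42, and the list adjusted p was 0.92; adjusted over the list alone 1 endothelial gene rose and 1 fell. The tests of the luminal, endothelial and androgen lists pointed up, while the luminal median was -0.039 and mean -0.09, the endothelial mean -0.083 and the androgen mean -0.045. No smooth muscle gene passed (list adjusted p = 0.912; Acta2 -0.42 and Mylk 0.22). Among prostate secretory products none of 4 genes passed (list adjusted p = 0.608), and 1 rose when adjusted over the list alone; C1s2 had a change of 3.32, with 9.54, 6.53 and 6.71 on the wild type arrays, and Pigr of 0.67, and a dimmer probe of C1s2, at the floor on all wild type arrays, rose at least 3.06-fold (limma adjusted p = 0.0152). Without wild type replicate 1 C1s2 (change 4.23, limma adjusted p = 0.00141) and Krt19 (-0.84, 0.0251) passed. Lists with fewer than 4 tested genes were not tested as lists. Among them, Lpl, the lipoprotein lipase gene of adipocytes, rose 2.05-fold (adjusted p = 0.0567 with 75th percentile scaling), and Car3 had a change of 1.01 on the log2 scale; with no floor 4 adipocyte genes were tested and the list passed, higher (adjusted p = 0.00667). Hbb-b1 rose 2.43-fold, Hba-a1 had a change of 1.31 on the log2 scale (limma adjusted p = 0.0573; 1.63 and 0.00751 without wild type replicate 3), and Upk3b was the 1 urothelial gene. No gene passed among the tested members of the neuroendocrine list (Calca -2.70, Syp -1.29), the nerve and Schwann cell list (Tubb3 -0.62, Prph -1.65), the T cell list (Cd3e 0.39), or the immediate early and endoplasmic reticulum stress lists, and no seminal vesicle gene was tested. Calca and Tubb3 lay at the floor on 2 knockout arrays; with a floor of 64 their changes were -1.83 and -0.01. Calca passed without wild type replicate 1 (change -3.68, limma adjusted p = 0.000784) but not without wild type replicate 3 (-2.11, 0.194). In the fit without wild type replicate 3 Syp (-1.91, 0.00767) and Prph (-2.74, 0.00919) passed, and without wild type replicate 1 Prph had a change of -0.98. Adjusted over the list alone, both red blood cell genes rose and 1 nerve gene fell. The interferon list (adjusted p = 0.608) and the oxidative phosphorylation list (adjusted p = 0.363) did not pass and had no gene past the threshold. The median change of the oxidative phosphorylation genes was -0.156, and -0.379 both without normalisation and with 75th percentile scaling, where the list passed, lower (adjusted p = 0.0219 and 0.0201); it also passed with array weights (0.0492) and without wild type replicate 1 (0.0107), so in 4 of 21 settings, with adjusted p up to 0.924. Of 8 proliferation genes 1 fell, or 3 when adjusted over the list alone (list adjusted p = 0.0995). The list passed, lower, with a floor of 16 (adjusted p = 0.0252) and without wild type replicate 1 (0.0365), 2 of 21 settings, with adjusted p up to 0.95. The gene that fell was Cdc20, named after its value was seen, which lay at the floor on all knockout arrays and was at least 1.84-fold lower. On the wild type arrays it was at 5.86, 5.63 and 6.15, near the floor, so the call rests on dim values.

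Skeletal muscle genes differed between wild type arrays and hardly between knockout arrays. Eno3 was at 8.12, 12.82 and 13.23 on the wild type arrays and at 10.32, 10.11 and 10.23 on the knockout arrays, and Casq1 at 5.26, 8.75 and 9.55 against 7.06, 6.82 and 7.03. Neither passed the test (changes -1.17 and -0.88, limma adjusted p = 0.649 and 0.67). Without wild type replicate 1 both passed, lower (changes -2.80 and -2.15, limma adjusted p = 0.00175 and 0.00978), and without wild type replicate 3 the changes were -0.24 and -0.04; without wild type replicate 2 that of Eno3 was -0.47. Over all tested probes the Pearson correlation between arrays, across probes, which are not independent replicates, was 0.987, 0.996 and 0.989 for the knockout pairs and 0.956, 0.937 and 0.970 for the wild type pairs. The first principal component, with 48.2% of the variance, separated the genotypes.

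**Figure D3:**
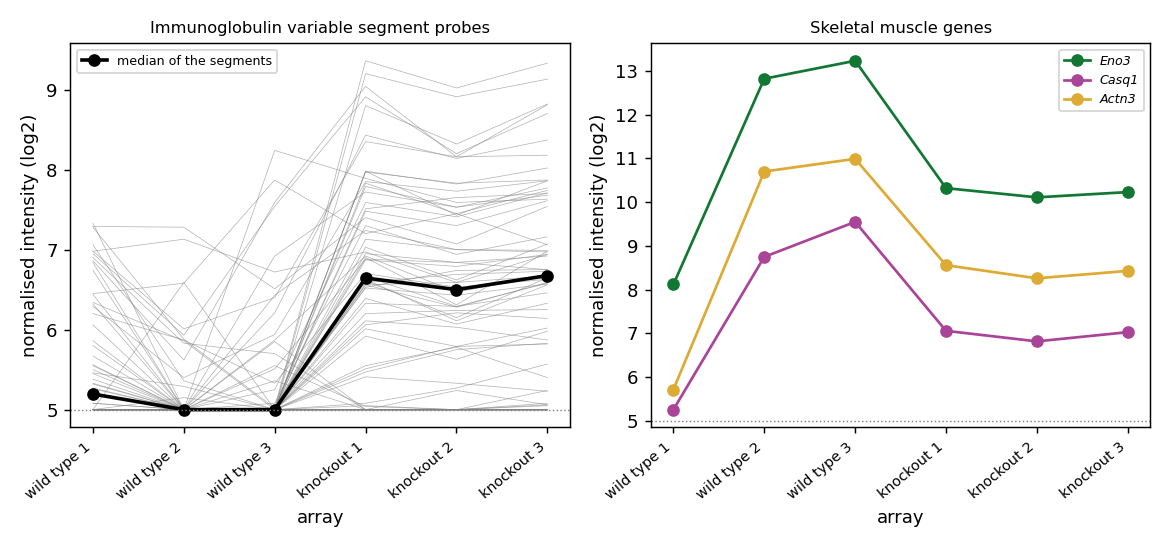
Normalised log2 intensity per array of 64 immunoglobulin variable segment probes (left; grey lines join the values of 1 probe, the black line is their median) and of 3 skeletal muscle genes (right). The dotted line is the floor at 5; the segment medians are 5 to 5.2 in wild type and 6.5 to 6.68 in knockout, and Eno3 spans 8.12 to 13.23 in wild type but 10.11 to 10.32 in knockout.

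Probe classes without gene names shifted too. Of 1679 tested RIKEN clone probes 261 were higher and 12 lower in the knockout, and 3 of 4 ribosomal RNA probes were lower; leaving out the RIKEN clone probes, a choice made after seeing the data, left 751 calls. The split of calls differed between settings: 66.8% were higher after quantile normalisation, 55.8% without it, 56.8% with 75th percentile scaling, 50.9% with array weights and 47.6% without wild type replicate 1 (994 higher and 1096 lower). Where few probes were called the share was larger. It was 85.7% of 49 without knockout replicate 1, 88.6% of 44 without knockout replicate 3 and 76.5% of 17 with the replicate block. The count of 1202 changed with the arrays used: it was 49 without knockout replicate 1, 44 without knockout replicate 3, 439 without knockout replicate 2, 581 without wild type replicate 2, 2090 without wild type replicate 1, 4489 with array weights, and 0 with all knockout arrays averaged into 1 sample (1838 probes at an unadjusted p under 0.05), the last chosen after seeing the data. The labels name 3 prostates per genotype but no animals, so the p-values measure the spread between these samples, which may be partly technical.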

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

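No group had the 4 samples needed to look for a sample far from the others, and there was 1 contrast and 1 table, so nothing was picked out by a fixed rule; the patterns here were chosen for weighing after the data were seen. The tests on variable segments and on splits of the arrays were also chosen after their results, or closely related values, were seen.

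The 3 knockout arrays were more alike than the 3 wild type arrays. Noisier measurement on the wild type arrays, where it strikes each probe singly, is argued against as the whole cause. Over 111 genes with 2 bright probes, the SD shared by both probes of a gene was 3.53 times as large in wild type pairs as in knockout pairs (95% bootstrap interval 2.41 to 5.58). The SD not shared by the probes was also larger, 1.52 times. Differences in RNA or labelling between samples would move both probes of a gene, so the test cannot weigh those. One labelled sample put on knockout arrays 1 and 3 stays open, because the differences of these arrays correlated between probes of a gene at 0.238 (95% bootstrap interval 0.068 to 0.383), above 0 but not wholly above the bound of 0.1. RNA of one animal or one pool also stays open: over 9 variable segments above the floor on every array, the SD of differences was at most 1.02 times that of matched probes in the knockout pairs and 1.11, 1.87 and 2.43 times in the wild type pairs, and the wild type pair at 1.11 shows that separate samples can pass the same test. The skeletal muscle gene Eno3 was at 10.32, 10.11 and 10.23 on the knockout arrays and at 8.12, 12.82 and 13.23 on the wild type arrays. Casq1 was at 7.06, 6.82 and 7.03 against 5.26, 8.75 and 9.55. Such close knockout levels would be seen with RNA of 1 animal or 1 pool, but this was not put to a test. A biological difference in spread between the genotypes is open as well and was not tested.

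RIKEN clone probes were higher and ribosomal RNA probes lower on the knockout arrays. Scaling that depends on intensity is argued against, since the median change of RIKEN clone probes lay 0.208 above that of gene-number probes of matched intensity, outside the range of 1000 draws. A difference in RNA preparation or labelling between the sets of arrays cannot be told apart from genotype: on the wild type array with the most 18S signal the RIKEN median lay at -1.797 relative to the gene-number median, against -1.800 and -1.752 on the other wild type arrays and -1.498 to -1.398 on the knockout arrays. An effect of the knockout on these transcripts was not tested apart from that.

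All 6 arrays can be split into 3 and 3 in 10 ways. The real split gave 1202 probes and was the 1 split with as many, and the highest of the others gave 0 with limma (128 to 2203 probes at an unadjusted p under 0.05); 10 splits are too few for a share under 0.05.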

How the results depend on the processing

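In the 38 named genes past the threshold all knockout arrays lay on one side of all wild type arrays, so leaving out or averaging arrays, or the block, could not turn their direction; none turned without normalisation or with 75th percentile scaling. Of the 38, 4, Ces5a, Crygc, Myh7 and Upk3b, were not tested under the stricter filter, and the setting without RIKEN clone probes was not run for named genes. Of the 38, 5, Aqp9, Ces5a, Crygc, Ighm and Mia, passed the threshold in each of the 6 fits without 1 array. The averaged and RIKEN settings were chosen after seeing the data. The count of 1202 probes was 4489 with array weights, 17 with the replicate block, 52 with knockout replicates 1 and 3 averaged, 0 with all knockout arrays averaged (1838 at an unadjusted p under 0.05), 751 without RIKEN clone probes, and 44 to 2090 without 1 array. The 38 called named genes became 58 with array weights, 4 with the replicate block, 5 with knockout replicates 1 and 3 averaged, 0 with all knockout arrays averaged, and 5 to 44 without 1 array. Leaving out or averaging arrays lowers the residual degrees of freedom, and leaving out any 1 array does so equally. The probe count was 49 and 44 without knockout replicates 1 and 3, but 2090 and 1670 without wild type replicates 1 and 3. Degrees of freedom alone therefore do not account for these falls, and their cause was not tested. The 3 lists past the test became 5 without normalisation, with 75th percentile scaling, with a floor of 16 and with no floor, 0 with an estimated correlation, and 1 to 5 without 1 array. The lists gained were BMP and TGF-beta in each of the first 4, with oxidative phosphorylation in the first 2, proliferation with a floor of 16 and adipocyte with no floor. With fry 2 lists passed, BMP and TGF-beta and FGF, IGF and PDGF, neither of them among the 3.

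Same-numbered arrays did not deviate together (correlations -0.082, 0.065 and 0.166 for numbers 1 to 3), and not every array correlated best with its own number. The values thus gave no sign of pairing by number. With 3 arrays per genotype they cannot exclude it. Named calls the block ended kept their change (Mt3 4.35). The test without a filter added 1 probe and is nearly void. No alternative was run for the level of Hoxc6, which no probe names. The floor limits the rest, since 67.2% of probes lay at it on each array. Quantile normalisation makes this share equal between arrays, and the choice of 32 sets its size. Before normalisation 21663 probes on wild type array 1 and up to 41903 on knockout array 3 were above the detection limit of their array.

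Some lists that did not pass turned direction, with these adjusted p; ranges cover all 6 fits without 1 array, whether or not they turned. Wnt: 0.986 without normalisation, 0.935 with a floor of 64, 0.916 with array weights, 0.841 without knockout replicate 2, the 1 fit without an array that turned (range 0.55 to 0.999). Luminal: 0.697 without normalisation, 0.659 with 75th percentile scaling, 0.916 with array weights, 0.969 with the replicate block, 0.998 with knockout replicates 1 and 3 averaged, 0.829 with fry, and 3 fits without an array (range 0.564 to 0.995). Apoptosis: 0.986 without normalisation, 0.99 with 75th percentile scaling, 0.961 with a floor of 16, 0.775 with array weights, and 2 fits without an array (range 0.725 to 0.996). Endothelium: 0.99 with 75th percentile scaling, 0.924 and 0.905 with the 2 averages, 0.810 with fry, and 3 fits without an array (range 0.753 to 0.995). Smooth muscle: 0.915 without wild type replicate 1 and 0.96 without wild type replicate 2 (range 0.479 to 0.995). Cldn4 had a change of -0.01 without normalisation and with 75th percentile scaling. The cause was not tested.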

Other observations

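The epididymis test below was chosen after values of some of its genes had been seen. Aqp9 and Ces5a, both known from the epididymis, were above the floor on all 3 knockout arrays. RNA of epididymis or deferent duct in the knockout samples is a candidate source, taken from a list of markers of these organs. Of the other 41 listed genes 4 had a probe, and 0 of those 4 were above the floor on all knockout arrays, with 1 probe of Defb15 at 5.47, 5.23 and 5; with so few genes held the test is void and the question stays open.

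Genes near Hoxc6 on its chromosome may differ between the groups because DNA around the targeted gene came from another strain. Of the 32 tested named genes nearest Hoxc6, 30 on one side and 2 on the other, 2 passed the threshold, Igfbp6 and Grasp, which was named after its values were seen; that is 6.25% against 4.52% of 4223 other genes (Fisher's exact test, two-sided p = 0.655, odds ratio 1.41, 95% interval 0.162 to 5.62). The interval covers both no excess and a large one, so this explanation stays open.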
